A study of Mus musculus with 8 samples.

How the data were processed

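The samples were 8 RNA-seq libraries of mouse cells captured with CD11b magnetic beads, 5 from medulloblastoma (TAMs) and 3 from normal cortex. Per the labels' protocols, tissue was digested with papain and depleted of myelin before capture. The groups and replicate numbers were taken from the sample titles. All results come from 1 deposited table of 38026 genes, which holds a column of TPM per library and 3 columns of the authors' own comparison.

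TPM values were computed by the authors, per the file headers, and each library's deposited TPM summed to between 990422 and 997832 over the genes listed. The genome build mm10, FastQC and DESeq2 are named in the submitters' processing notes, without versions. The aligner, the quantifier, the annotation release and the strandedness of the libraries are not given in the sources used here. The authors' deposited table also holds the DESeq2 mean signal per gene, the log2 fold change and an unadjusted p-value, per the file headers. Of the deposited p-values 27039 were given, 203 genes had a fold change without a p-value and 10784 had neither. No counts or depths per library were given, so the precision due to depth is unknown. A further 3 unnamed columns with stray entries were not used. In 27 rows a spreadsheet had turned the gene symbol into a date, and 28 symbols were duplicated, so genes were followed by their Ensembl identifier.

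Because the table holds TPM and not counts, the count test planned for counts was not used. Genes with at least 1 TPM in at least 3 libraries were kept (15262) and tested with limma 3.58.1 with an intensity trend, in R 4.3.3, on log2(TPM + 1), with all 8 libraries in 1 fit and no covariate. P-values were adjusted by Benjamini-Hochberg at 0.05. Gene lists (34, with 677 genes, of which 8 were not matched in the table) were fixed before the data were examined. They were tested with camera at its preset correlation of 0.01 and again with an estimated correlation. The genes named in the text follow a rule also fixed beforehand. It takes the 10 largest rises and the 10 largest falls among called genes with at least median expression and no overlap between groups, up to 4 called genes of lowest p per list, and a set of genes chosen in advance. This gave 148 genes. Genes outside the rule, named where a count was 5 or fewer, were chosen after their values were seen. Some genes that the rule takes are not reported here.

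A median-ratio rescaling of TPM was added after the data were seen, because the median log2 fold change over all genes was -0.65. The 3 features Mir6236, Mir6240 and Gm15662 took 13.5% to 25.5% of TPM in TAMs and 3.18% to 15.3% in microglia. Without them the median was still -0.50, and on coding genes alone -0.48, so these features accounted for only part of the shift. The sums of near-identical copies were also added after the data were seen. Of 525 copies searched, 274 matched a coding transcript of the GENCODE M21 annotation at 95% identity or more over 80% or more of the copy (blastn 2.17.0), giving 224 families. Coordinates are those of the deposited table, on mm10, and 99.9% of the genes overlapped the same gene of the reference.

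The fit was tested on simulated data of 15262 genes with 200 changed. It recovered 61.3% of the genes changed by a log2 of 1, 85.5% of those changed by 2 and 96.9% of those changed by 4, with 6 false genes among 165 calls. The simulated genes varied independently and had no shift common to all genes. These rates therefore do not cover the shift between the groups seen here. Alternatives covered the scaling, the filter, the pseudocount, the age of the mice, a replicate block, a fold threshold, the near-identical copies and leaving out each library in turn. Correlations of log2(TPM + 1) across genes were 0.921 to 0.965 within TAMs, 0.942 to 0.973 within microglia and 0.781 to 0.882 between them, so no libraries held identical values.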

Results

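Bulk RNA-seq was available for 8 mouse libraries of cells captured with CD11b magnetic beads, CD11b being an integrin subunit carried by microglia, macrophages, monocytes and granulocytes. In 5 libraries the cells were tumor-associated microglia and macrophages (TAMs) taken from medulloblastoma, a tumor of the cerebellum, in mice aged 61, 62, 66, 68 and 90 days after birth. In the other 3 libraries the cells were microglia from normal cerebral cortex of mice aged 60 days. The values were TPM (transcripts per 1000000), with 12683 to 14242 genes at 1 TPM or more in the TAM libraries and 14375 to 16619 in the microglia libraries. TPM keeps no read depth, so the depth of each library is unknown and no counting interval is given.

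The design implied 1 comparison: how gene expression in TAMs differs from that of normal microglia. TAMs carried far more RNA of genes known from microglia around damage and in lipid-laden macrophages, led by Cst7, Gpnmb, Apoc1, Spp1, Lgals3 and Clec7a. Genes that mark resting microglia, such as P2ry12, Tmem119 and Slc2a5, were lower. Of the cell division genes 31 of 36 were higher in TAMs, of lysosome genes 19 of 34 (3 lower), of MHC class I genes 11 of 19, of MHC class II genes 8 of 15 (1 lower) and of interferon genes 11 of 30. The camera calls of these lists were lost with an estimated correlation (adjusted p = 0.119, 0.119, 0.165, 0.0570 and 0.255). Igf1, which encodes insulin-like growth factor 1, was higher too. Markers of endothelial cells, mural cells, astrocytes and oligodendrocytes were mostly higher in the cortex libraries.

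Of 15262 genes tested with limma on log2(TPM + 1), 1254 were higher and 8610 lower in TAMs at an adjusted p of 0.05. The median log2 fold change over all tested genes was -0.65 on this scale, so most genes were listed lower in TAMs. On rescaled TPM, a scale chosen after the data were seen that divides each library by its median ratio to the mean library, the median was -0.04, with 3755 genes higher and 3837 lower. The share of higher genes among the calls was 12.7% on TPM and 49.5% on rescaled TPM. On both scales 1247 genes were higher and 3837 lower, while 219 genes were called in opposite directions. In 57.7% of the genes the TPM values of the groups did not overlap, against 3.57% by chance. The shift of most genes can raise this share, which was not computed on rescaled TPM. Log2 fold changes below are on log2(TPM + 1), which understates the change of low genes, and changes that hold relative to the median shift are given through the rescaled counts. In the authors' deposited table, the DESeq2 p-values adjusted here by Benjamini-Hochberg gave 4763 genes higher and 4324 lower. Of 4696 genes called both there and on TPM, 4322 had the same sign and 374 the opposite one. All 6772 called both there and on rescaled TPM had the same sign. The deposited fold changes come from the same libraries, and their median over the tested genes was 0.09, also near 0. The shared signs are therefore no independent support for the rescaling.

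Igf1 (chromosome 10, 87858265 to 87937042 on mm10) was at 111 ± 58.4 TPM (SD, n = 5) in TAMs and 12.1 ± 3.14 TPM (SD, n = 3) in microglia. Its log2 fold change was 2.86 with an SE of 0.59 (limma, adjusted p = 0.00333), and it was higher in 5 of 5 TAM libraries than in any microglia library. TAM replicate 1 was the lowest at 23.7 TPM and TAM replicate 3 the highest at 177 TPM. Of the 12 tested genes of the IGF axis, Igf1 was the 1 that rose, while 10 fell, 8 of them also on rescaled TPM. Igfbp7, which binds IGFs, fell by 4.40 and the insulin receptor gene Insr fell by 1.64 on the log2 scale. Camera did not call this list (adjusted p = 0.368), but did on rescaled TPM (adjusted p = 0.0336), a call lost without TAM replicate 1 (adjusted p = 0.0618). With an estimated correlation the adjusted p was 0.780. Without microglia replicate 2 or 3, 5 genes of the axis were lower on rescaled TPM. Igfbp7 is also abundant in brain vessels, whose markers were lower in the same libraries. Of 25 growth factor genes 4 rose and 14 fell (4 and 9 rescaled), without a camera call (adjusted p = 0.927). Leaving out any 1 microglia library left 20 of them tested, with 7 to 9 lower (3 rescaled). The 4 that rose were Igf1, Hgf, Pdgfc and Lif, of which all but Igf1 fall outside the naming rule.

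**Figure D1:**
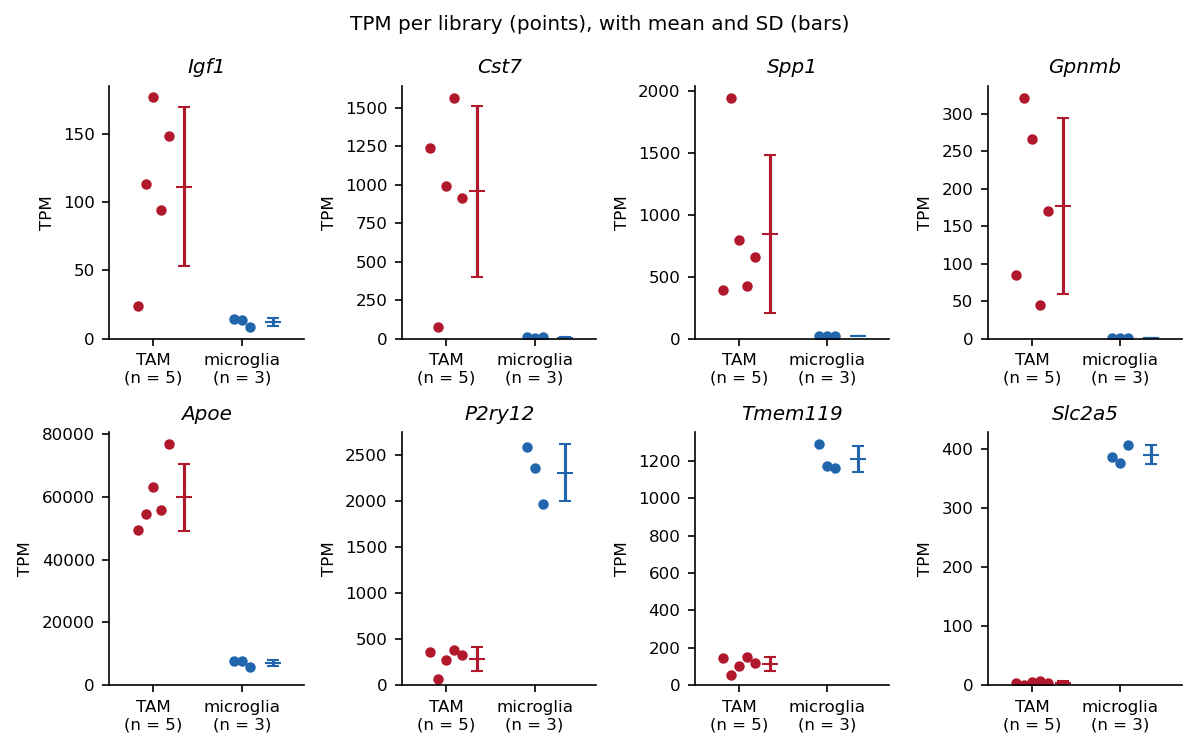
TPM of 8 genes in each library, with the y axis in TPM from 0, points for libraries (red TAM, n = 5; blue cortex microglia, n = 3) and bars for mean and SD. Igf1, Cst7, Spp1, Gpnmb and Apoe are higher in TAMs and P2ry12, Tmem119 and Slc2a5 lower, with no overlap between groups; Cst7 is at 75.0 TPM in TAM replicate 2.

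Among 30 tested genes of damage-associated microglia, 25 rose and 1 fell (26 and 0 rescaled; camera adjusted p = 1.62e-28, and 0.0287 with an estimated correlation). Cst7 (chromosome 2, 150570415 to 150578944), a cystatin, rose from 6.43 ± 1.47 to 955 ± 553 TPM (log2 fold change 6.51, SE 0.90, adjusted p = 0.000577). Gpnmb, a lysosomal membrane glycoprotein, rose from 0.806 ± 0.148 to 178 ± 117 TPM, and the lipoprotein gene Apoe from 7069 ± 1062 to 59916 ± 10694 TPM. Apoe alone made up 5.99% of TPM in TAMs and 0.707% in microglia. The 1 that fell was Ccl3 (log2 fold change -0.93, and -0.21 without a call rescaled). Of 25 genes of lipid handling, 16 rose and 3 fell (18 and 1 rescaled; adjusted p = 2.84e-16, and 0.0342 with an estimated correlation). Apoc1 (log2 fold change 5.90), Apoc2 (4.47), the lipase Lpl (4.29) and the lipid droplet gene Plin2 (2.78) were among those that rose. Nr1h2, Pltp and Acsl1 fell, with 1 lower gene without microglia replicate 2 or 3. Lysosome genes rose in 19 of 34 and fell in 3 (27 and 0 rescaled; adjusted p = 4.62e-17, but 0.119 with an estimated correlation). Ctsb, a cathepsin, rose by 2.23 and the galactosidase Glb1 by 2.01, while Tfeb, Neu1 and Laptm5 fell on TPM alone, and 5 genes were lower without TAM replicate 2 or microglia replicate 1. Of 22 cholesterol synthesis genes 18 fell (9 rescaled, with Dhcr7 and Mvd higher there) and camera did not call the list (adjusted p = 0.0551). It did without TAM replicate 2 or any 1 microglia library (adjusted p = 0.0170 to 0.0473), and without microglia replicate 3, 5 genes were lower rescaled.

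Of 27 genes of resting microglia 22 fell and none rose (15 fell rescaled; camera adjusted p = 0.00254, but 0.612 with an estimated correlation). Slc2a5, a fructose transporter (chromosome 4, 150119283 to 150144169), was at 390.3 ± 15.6 TPM in microglia and 3.66 ± 2.39 TPM in TAMs (log2 fold change -6.60, SE 0.49, adjusted p = 4.87e-05). The purinergic receptor P2ry12 (log2 fold change -3.25), Tmem119 (-3.49), Csf1r (-1.70) and Cx3cr1 (-1.53, and -0.81 rescaled) fell on both scales, while Cx3cr1 was not called in the authors' deposited table (DESeq2 adjusted p = 0.0530). Itgam, which encodes CD11b itself, fell by 1.75 and Aif1 rose by 0.70. Ptprc, which encodes CD45, changed by 0.17 without a call (adjusted p = 0.503) and was called higher on rescaled TPM at 0.89. Monocyte-derived macrophage genes rose in 10 of 25 and fell in 2 (13 and 2 rescaled; adjusted p = 1.45e-09, but 0.165 with an estimated correlation), with Itgal at 3.86 and Lyz2 at 3.36. Fn1 and Ahnak fell. TAM replicate 2 stood apart on both lists, with a mean of 6.07 on the monocyte-derived list against 4.67 to 5.00 in the other TAM libraries and of 6.30 on the resting list against 7.61 to 8.02. Without it, 10 monocyte-derived genes were higher and 5 lower, and 26 resting genes lower. Ccr2 (1.21, adjusted p = 0.149) and Mrc1 (-1.02, adjusted p = 0.0592) did not pass. Border macrophage genes went both ways, 6 higher and 9 lower of 20 (6 and 6 rescaled; adjusted p = 0.126), with a median log2 fold change of -1.13 although camera placed the list above the remaining genes. Without microglia replicate 1, 3 were lower rescaled.

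Interferon genes rose in 11 of 30 with none lower (18 rescaled; camera adjusted p = 1.23e-13, but 0.255 with an estimated correlation). Bst2 rose by 2.43 and the antiviral gene Rsad2 by 2.54, and the list mean ranged from 3.78 in TAM replicate 2 to 6.22 in TAM replicate 1 on the log2 scale. Higher interferon genes numbered 6 to 8 without 1 microglia library (8 to 11 rescaled) and 11 rescaled without TAM replicate 4. MHC class I genes rose in 11 of 19 with none lower (16 rescaled; adjusted p = 2.56e-11, but 0.165 with an estimated correlation), including H2-D1 at 1.67 and the transactivator Nlrc5 at 2.01, and in 7 without microglia replicate 1 or 2. MHC class II genes rose in 8 of 15 and fell in 1 (9 and 0 rescaled; adjusted p = 1.45e-09, but 0.0570 with an estimated correlation). H2-Aa rose from 188 ± 50.9 to 1476 ± 649 TPM and Cd74 by 2.54 on the log2 scale. The 1 that fell was Cd80. Complement genes rose in 7 of 19 and fell in 4 (10 and 3 rescaled; adjusted p = 5.86e-06, but 0.104 with an estimated correlation), with C3 at 3.80. Serping1, Itgam and Cd55 were among those that fell. The rescaled call of this list was lost without TAM replicate 4 (camera adjusted p = 0.0553) or microglia replicate 3 (0.0533).

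Inflammatory cytokine and NF-kB genes split into 5 higher and 12 lower of 22 (6 and 6 rescaled; camera adjusted p = 0.461), with a negative median and a positive camera direction. Il1rn, which encodes a decoy ligand of the IL-1 receptor, rose by 3.60, with Il1b, Ptgs2, Cd40 and Bcl2a1b also higher, while the NF-kB inhibitors Nfkbia and Tnfaip3 had log2 fold changes of -2.60 and -1.32 (-1.88 and -0.60 rescaled). Tnfaip3 was not called in the authors' deposited table (log2 fold change -0.52, DESeq2 adjusted p = 0.0741). Without microglia replicate 1 or 3, 3 genes of the list were lower rescaled. Chemokine genes also split, 7 higher and 9 lower of 22 (8 and 5 rescaled; adjusted p = 0.0132, but 0.255 with an estimated correlation). Their median was -0.43 while camera ranked them above other genes. Ccl8 rose by 4.09 and Ccl24 fell by 3.42, and the call was lost on rescaled TPM (adjusted p = 0.575) and without microglia replicate 2 (adjusted p = 0.0741). Of 24 genes of the response to IL-4, 10 rose and 6 fell (12 and 4 rescaled). The camera call of that list (adjusted p = 0.000170) was lost with an estimated correlation (adjusted p = 0.165) and on rescaled TPM (adjusted p = 0.136), and without 1 microglia library 5 or 6 of its genes were higher (7 to 9 rescaled, and 2 lower rescaled without microglia replicate 2). Il4ra, a receptor subunit for IL-4, was at 75.5 ± 3.92 TPM in TAMs and 41.8 ± 5.85 TPM in microglia (log2 fold change 0.85, SE 0.11, adjusted p = 0.000432), while Irf4 fell by 2.11. Immune regulation genes rose in 5 of 18 and fell in 6 (9 and 2 rescaled; adjusted p = 0.0158, but 0.124 with an estimated correlation), with a median of -0.11 under a positive camera direction and the call lost on rescaled TPM (adjusted p = 0.0780). Cd274, Il10, Arg1, Lilrb4a and Marco rose. Without 1 microglia library 2 or 3 genes of this list were higher (3 or 4 rescaled), as were 5 rescaled without TAM replicate 1, 3 or 4, and without microglia replicate 2 its call was lost (adjusted p = 0.0781). Tgfb1 of this list fell by 0.64 on TPM and stood at 0.080 on rescaled TPM.

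Cell division genes rose in 31 of 36 with none lower (35 rescaled; camera adjusted p = 1.30e-34, but 0.119 with an estimated correlation). Cdk1 rose from 11.2 ± 2.24 to 46.5 ± 6.88 TPM, Ube2c by 2.36 and Plk1 by 1.98 on the log2 scale. Glycolysis and hypoxia genes rose in 11 of 26 and fell in 8 (15 and 1 rescaled; adjusted p = 2.01e-07, but 0.165 with an estimated correlation). Pkm rose by 1.47, and the glucose transporter Slc2a1, also on the endothelial list, fell by 2.67. Without microglia replicate 1 the lower genes were 5 and without replicate 3 they were 3, while without TAM replicate 2 the 1 lower rescaled gene became 4. Matrix genes rose in 10 of 25 and fell in 9 (10 and 5 rescaled; adjusted p = 1.91e-05, but 0.165 with an estimated correlation), with Spp1 at 5.06 and Adamts1 at -4.99, and without microglia replicate 2 or 3, 3 were lower rescaled. On rescaled TPM camera did not call this list (adjusted p = 0.105). Of 17 genes of the granule neuron lineage and Hedgehog-driven medulloblastoma, 4 rose and 4 fell (5 and 4 rescaled; adjusted p = 0.0298, but 0.652 with an estimated correlation). Atoh1, Barhl1, Neurod1 and Insm1 rose and Ptch1, Zic2 and Ccnd1 were among those that fell. Higher genes of this list numbered 2 without TAM replicate 1 or 4 (3 rescaled) and 1 without any 1 microglia library (1 or 2 rescaled). Its call was lost on rescaled TPM (adjusted p = 0.901) and without TAM replicate 1, 4 or 5 or microglia replicate 1 (adjusted p = 0.0601 to 0.0666). The list mean was 2.81 in TAM replicate 5 against 0.92 to 1.43 in the other TAM libraries.

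**Figure D2:**
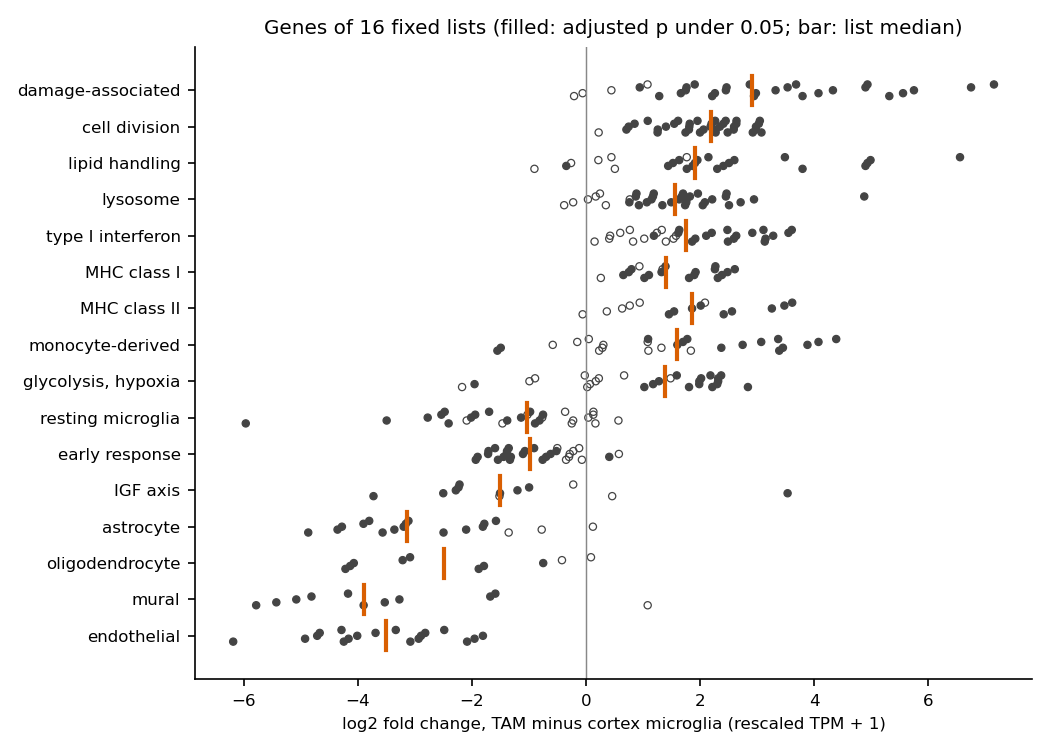
Log2 fold change of TAMs over cortex microglia on rescaled TPM (x axis) for the tested genes of 16 gene lists (y axis), filled where the adjusted p is under 0.05, with a bar at each list median. The damage-associated list has a median of 2.91 and the endothelial list one of -3.51.

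Endothelial markers were lower in TAMs in 18 of 18 (18 rescaled; camera adjusted p = 4.36e-05, but 0.443 with an estimated correlation), mural markers in 10 of 11 (10 rescaled; adjusted p = 0.00155, but 0.464 with an estimated correlation). Astrocyte markers were lower in 16 of 18 (15 rescaled; adjusted p = 0.00981, but 0.652 with an estimated correlation) and oligodendrocyte markers in 9 of 10 (8 rescaled; adjusted p = 0.0116, but 0.481 with an estimated correlation). When 1 microglia library was left out fewer markers reached 1 TPM in 3 libraries. Lower were then 9 to 11 of 11 or 12 tested astrocyte markers (8 to 10 rescaled), 6 or 7 of 8 mural ones, and 6 or 7 of 7 oligodendrocyte ones (4 or 5 rescaled), against 18 of 18 endothelial ones. The astrocyte call was lost without TAM replicate 5 (adjusted p = 0.0591). Ly6c1, an endothelial surface gene (chromosome 15, 75044018 to 75048830), was at 497 ± 254 TPM in microglia and 4.70 ± 6.27 TPM in TAMs (log2 fold change -6.81, SE 0.71, adjusted p = 0.000190). Acta2, a smooth muscle actin, fell by 6.32 and the astrocyte gene Gfap fell by 4.53. Vtn, Rgs5, Slco1c1, Slco1a4, Clu, Mgp and Ptgds, among the largest falls, are vessel, meningeal or glial genes. Early response genes, which rise during tissue dissociation, were lower in TAMs in 26 of 28 with none higher (19 lower and 1 higher rescaled; adjusted p = 6.57e-06, but 0.165 with an estimated correlation). Klf2 was the gene called higher on rescaled TPM. Zfp36 was at 2849.6 ± 119 TPM in microglia and 665 ± 107 TPM in TAMs.

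Neutrophil markers rose in 6 of 12 and fell in 2 (7 and 0 rescaled; camera adjusted p = 5.86e-06, but 0.165 with an estimated correlation), with S100a8 at 2.85 and with Mmp9 and Csf3r lower on TPM alone. The list mean was 4.59 in TAM replicate 2 against 2.80 to 3.24 in the other TAM libraries, and without it 6 markers were higher. B and plasma cell markers rose in 3 of 6 and fell in 2 (4 and 1 rescaled; adjusted p = 0.00195, but 0.104 with an estimated correlation). Igkc, an immunoglobulin light chain gene, rose from 4.45 ± 4.79 to 195 ± 241 TPM, with 591 TPM in TAM replicate 3, 261 in replicate 1 and 28.0 to 53.5 in the other 3. Its log2 fold change was 4.59, and 3.95 without TAM replicate 3, still called. T and NK cell markers rose in 3 of 10 and fell in 3 (4 and 2 rescaled; adjusted p = 0.0125, but 0.124 with an estimated correlation). Cd4, at 24.2 to 104 TPM, and Klrk1, at 1.74 to 9.49 TPM, were higher in every TAM library than in any microglia library. Lck was lower in every TAM library. Cd3d, Cd3e and Cd3g of the same list, chosen after their values were seen, were at 0.0219 to 1.56 TPM in TAMs. The T and NK cell list therefore did not move as 1 unit, and its counts do not show that such cells were more frequent in TAMs. Both the B and plasma cell call and the T and NK cell call were lost on rescaled TPM (camera adjusted p = 0.129 and 0.514). The remaining cell type lists were not called by camera. Neuron markers had 1 higher and 8 lower of 12 (2 and 6 rescaled; adjusted p = 0.927), dendritic cell markers 2 and 4 of 12 (3 and 3; adjusted p = 0.0551) and erythroid markers 0 and 3 of 4 (0 and 1; adjusted p = 0.804). Oligodendrocyte precursor markers had 0 higher and 4 lower of 5 (0 and 1; adjusted p = 0.789) and choroid plexus markers 0 and 1 of 2 (0 and 1; adjusted p = 0.807). The neuron, dendritic cell and choroid plexus lists had negative medians and a positive camera direction, and Tubb3 was the neuron marker that rose. With 1 microglia library left out, 4 or 5 neuron markers were lower (2 to 4 rescaled), 1 or 2 erythroid markers, 0 or 1 T and NK cell markers and 1 B and plasma cell marker. Higher on rescaled TPM were then 1 or 2 T and NK and 2 B and plasma cell markers, the latter also without TAM replicate 1. Precursor markers had none lower without microglia replicate 2 or 3, and the dendritic list had 1 higher gene. Camera called the dendritic list without TAM replicate 3, 4 or 5 (adjusted p = 0.0131 to 0.0420).

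**Figure D3:**
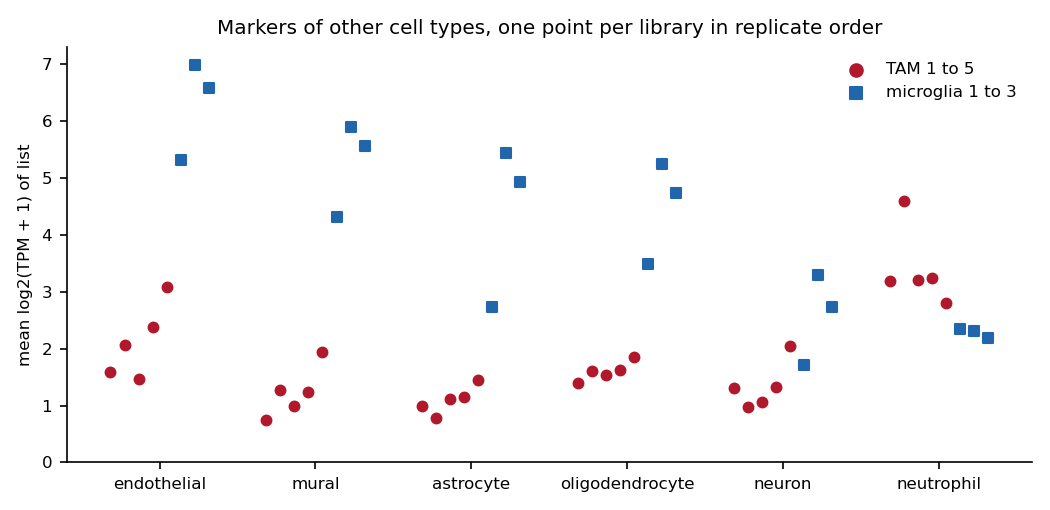
Mean log2(TPM + 1) of 6 marker lists (y axis) in each library, with red circles for TAM replicates 1 to 5 and blue squares for microglia replicates 1 to 3. The endothelial mean lies between 5.32 and 6.99 in microglia and between 1.47 and 3.08 in TAMs, and the neutrophil mean is 4.59 in TAM replicate 2.

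Rpl3 had the largest log2 fold change of the named genes (7.57), but it has a copy 99.83% identical, Rpl3-ps1. How the authors' counting divided reads between such copies is not given in the sources used here, so its value is uncertain. Rpl3 was at 629 ± 218 TPM in TAMs and 2.17 ± 0.573 TPM in microglia, while the sum of Rpl3 and its copy was 766 ± 61.4 and 692 ± 35.8 TPM (log2 fold change 0.14, SE 0.10, limma adjusted p = 0.226). On rescaled TPM this sum was called higher at 0.87 (limma adjusted p = 0.00210). Rpl17-ps5 fell by 5.48 while its sum with Rpl17 stood at 0.03 (0.76 rescaled, where it was called). In the authors' deposited table Rpl3 ranked 1 by p-value.

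**Figure D4:**
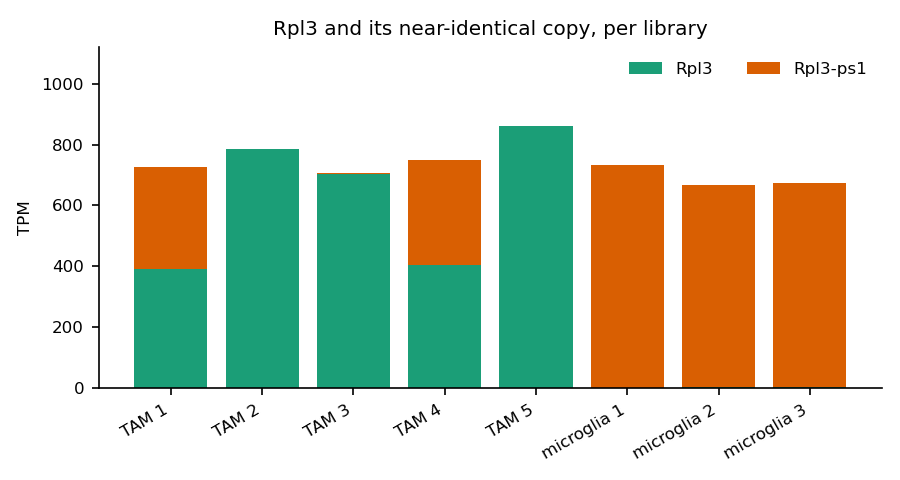
TPM of Rpl3 (green) and Rpl3-ps1 (orange), stacked from 0, in each library. The sum stays between 669 and 862 TPM while its division between gene and copy differs, with TAM replicates 1 and 4 holding 336 and 346 TPM of Rpl3-ps1.

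Adjusted over the list alone, the counts were 23 lower for resting microglia, 12 lower for border macrophages, 11 higher and 8 lower for IL-4, 9 higher for interferon and 17 higher for lipid handling. They were 2 higher for the granule neuron lineage, 17 lower for astrocytes and 7 higher for neutrophils, and in all other lists equal to those over all genes. Camera called 24 of the 34 lists with its preset correlation and 2 with an estimated one, the damage-associated and lipid handling lists, and other splits of the libraries called up to 24. Of the tested genes of these lists, 21 of 30 and 8 of 25 also stood on another list. Cut to the rest, a test added after the data were seen, 8 of 9 damage-associated genes rose (camera adjusted p = 0.0193 with an estimated correlation). Of 17 lipid handling genes 10 rose and 3 fell, without a call (adjusted p = 0.0642 with an estimated correlation). Cut in the same way, the chemokine list was not called with the preset correlation (adjusted p = 0.0876), and complement was not called on rescaled TPM (adjusted p = 0.0772). An exact permutation test of each list mean over the 56 splits took libraries as the unit. It was two-sided, on rescaled TPM and chosen after the data were seen. Unlike camera, it did not compare a list with the other genes. It placed 21 lists at 0.0179, the smallest p the splits can give (adjusted p = 0.0289), 15 higher and 6 lower in TAMs. Of the lists called by camera on TPM, resting microglia and interferon (each adjusted p = 0.0506), chemokines (0.0837) and the granule neuron lineage (0.804) were not among them. The IGF axis was, as lower in TAMs. So were, as higher, the IL-4, matrix, immune regulation, T and NK cell and B and plasma cell lists, whose camera calls were lost on rescaled TPM. The permutation test asks a different question and does not restore those calls. Cut to its 9 tested genes on no other list, IL-4 had 3 higher and 2 lower on TPM (camera adjusted p = 0.318 rescaled). Resting microglia and interferon each had an unadjusted permutation p of 0.0357, and their list means on TPM did not overlap between the groups. The resting means were 9.48 to 9.60 in microglia and 6.30 to 8.02 in TAMs, the interferon means 3.38 to 3.63 and 3.78 to 6.22. Tissue and group were not separable in this design. All microglia came from mice of the same age, and with age as a covariate 1194 genes were higher and 7395 lower (3398 and 3421 rescaled), with Igf1 at 2.93 (limma adjusted p = 0.0105). The TAM libraries came from mice of different ages, and so from separate mice. The labels do not say whether the microglia libraries did, so the p-values measure the spread between these libraries. All 3 microglia libraries, but no TAM library, held both Xist and Ddx3y above 10 TPM. If the microglia libraries were pools, a candidate explanation given below, their spread is not that between single mice.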

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

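The tests of explanations in this part were chosen after the results they concern had been seen. Among 182 sets of 5 TAM values (148 named genes and 34 list means), 15 had a library far from the other 4 by Dixon's rule, where chance gives about 1 in 20, or 9.1. Of these, 7 fell on TAM replicate 2, from the mouse aged 90 days, 7 on TAM replicate 5 and 1 on TAM replicate 1.

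In TAM replicate 2, Cst7 was at 75.0 TPM against 912 to 1562 in the other TAM libraries, P2ry12 at 65.0 against 268 to 382, Hpse at 31.1 against 90.2 to 136 and Ctsb at 2445 against 4016 to 4790. Its list mean on the log2 scale was 6.30 for resting microglia against 7.61 to 8.02, 6.07 for monocyte-derived macrophages against 4.67 to 5.00 and 4.59 for neutrophils against 2.80 to 3.24. In TAM replicate 5 the granule neuron lineage list mean was 2.81 against 0.92 to 1.43. Mal was at 2.37 TPM there against 0.0273 to 0.435, Pdgfra at 1.96 against 0.363 to 0.647, Nrgn at 0.361 against 0.0358 to 0.0857 and Ntsr2 at 0.0848 against 0.0263 to 0.0419. Ebf1 was at 3.35 against 0.445 to 0.891 and Acat2 at 6.69 against 4.15 to 4.72. In TAM replicate 1 Psmb8 was at 243 TPM against 166 to 185.

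Changes of 8-fold or more were called in 21 genes that have a near-identical copy or are such a copy, in 20 families, with a median absolute log2 fold change of 4.60. In 19 of the 20 families the TPM summed over gene and copies changed by less than a log2 of 3 beyond 2 SE. A family was taken when any 1 member changed 8-fold, so a sum holding a gene that barely moved could hardly reach that size. Cox7a2l and Pcna alone, for example, changed by 0.02 and 0.03, and for such families the sums decide nothing. Rpl3 alone changed by 7.57 but its sum by 0.14 (SE 0.10), which argues against a change of that size in its total RNA. The sums do not argue against smaller changes, since those of 11 families were themselves called, and of 14 on rescaled TPM. Reads shared between near-identical copies remain a candidate explanation, with a median absolute log2 fold change of the sums of 0.32, and of 0.75 on rescaled TPM, where the genes themselves had 4.07. Hspb1, a small heat shock gene, is the exception, since its sum with its copy changed by -3.75 (SE 0.24), which argues against shared reads there, although on rescaled TPM the sum, at -3.04 (SE 0.16), was within 2 SE of the bound of 3.

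Markers of vessels, astrocytes and myelin were higher in the cortex libraries, with 51 of 57 markers, or 89.5%, called lower in TAMs on rescaled TPM, and with Ly6c1 at 497 TPM and Gfap at 115 TPM in microglia. A lower share of microglia in the cortex libraries that raises every other cell type alike would by itself put the neutrophil list below 0. The median rescaled log2 fold change of that list was 1.41 (95% bootstrap interval over genes 0.48 to 3.08), and 1.04 without TAM replicate 2 (0.24 to 2.63). That interval takes genes as independent, and camera did not call the list with its estimated correlation of 0.382 (adjusted p = 0.165), but with libraries as the unit the list means differed by 1.62 (Welch 95% interval 0.68 to 2.57), and by 1.31 (0.75 to 1.87) without TAM replicate 2. Neutrophils carry CD11b and may be more frequent in tumors, which could raise this list whatever the share of microglia. The list therefore cannot decide the explanation of a lower microglial share. RNA from other brain cells in the cortex libraries and a difference between cortex and tumor tissue cannot be told apart by that 89.5%, since each group came from 1 tissue.

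Xist, transcribed from the inactive X of females, and Ddx3y, a gene of the Y, were both above 10 TPM in 3 of 3 microglia libraries. No TAM library had both, with Xist alone in replicates 2 and 4 and Ddx3y alone in replicates 1, 3 and 5. Cortex libraries pooled from mice of both sexes are a candidate explanation. It was drawn from these same values, so the presence of both transcripts in all 3 libraries adds no support for it. No biological explanation was tested.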

How the results depend on the processing

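The median-ratio rescaling and its own alternatives, the removal of 3 features, the restriction to coding genes and the sums of copies were chosen after seeing the data. The 1254 higher genes became 4131 with quantile normalization, 3152 with upper-quartile scaling, 3755 with median-ratio rescaling and 429 with a 1.5-fold threshold. The 8610 lower genes became 3528, 4606, 3837 and 3153. Without the 3 features 1723 genes were higher and 7548 lower, and on coding genes alone 1589 and 6750. Leaving out each library in turn gave 894 to 1303 higher and 5581 to 9243 lower genes, with 5581 without microglia replicate 2. On rescaled TPM a 1.5-fold threshold left 1078 higher and 1243 lower. Leaving out each library gave 2485 to 3943 higher and 2144 to 4068 lower there, with 2485 and 2144 without microglia replicate 3 and 2260 lower without microglia replicate 2. Those fits have fewer libraries, and the cause was not tested further. The 24 lists became 2 with an estimated correlation. Tgfb1 reversed from -0.64 to 0.080 under median-ratio rescaling, where it was not called, and the cause was not tested beyond the shift of all genes. Among 147 further named genes, 7 lower ones lost their call under each of quantile, upper-quartile and median-ratio scaling and none of the higher ones did. These scalings raised the median log2 fold change from -0.65 to 0.06, -0.16 and -0.04. Higher genes were therefore unlikely to lose their call, and the difference says little on how stable they are. Igf1 was called under every alternative run, with a log2 fold change of 2.26 to 3.54. DESeq2, edgeR and voom were not run, because they need counts. The shared replicate numbers did not pair the libraries (correlations 0.15, 0.01 and -0.05), and with the replicate block 1103 genes were higher and 8613 lower, with Igf1 at 2.63. 

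No other split of the 8 libraries into 5 and 3, of 56, gave as many genes as the real 1. That share, 1 of 56, is the smallest the splits can give. It argues against chance for the gene counts but cannot exclude it. It does not bear on tissue, which divided the libraries in the same way as group. The real counts were 1254 higher and 8610 lower, and the highest others 6 and 22. On rescaled TPM the real counts were 3755 and 3837, and the highest others 10 and 10. The splits did not argue against chance for the number of lists called, which 3 of the 56 splits reached (24, highest other 24). For rescaled TPM 10 splits reached the real 18 (highest other 22), and with an estimated correlation 9 splits reached the real 2 (highest other 14).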

Other observations

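Gapdh, a glycolysis gene often used as a reference, was higher in TAMs when summed with its 4 near-identical copies, at 1435 to 2387 TPM in TAM libraries against 593 to 690 TPM in microglia. Gapdh alone was listed at 86.7 to 1078 TPM in TAMs and at 60.1 to 75.0 TPM in microglia. This feature was singled out after its values were seen.

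Atoh1, a gene of cerebellar granule neuron precursors, was listed at 0 in all 3 microglia libraries and at 0.238 to 6.27 TPM in the TAM libraries, the highest in TAM replicate 5. It too was singled out after its values were seen. Among B cell markers, Cd22 rose from 1.45 ± 0.0384 to 43.4 ± 6.74 TPM while Ighm fell by 0.82 on TPM and was not called on rescaled TPM, so the list did not move as 1 unit.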
